A study of Rattus norvegicus with 12 samples.

How the data were processed

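RNA of 12 samples of neonatal rat aortic smooth muscle cells was labelled with biotin and hybridised to 1-colour Affymetrix arrays of 31099 probe sets. Per the labels, the deposited values are intensity on a linear scale, made by the authors with GCOS 1.4 according to the submitters' processing notes. The values show a scaling per array to a mean of about 200 once the lowest and highest 2% are left out, no missing values and no further normalization between arrays. Detection calls were not used here, so no fold is given as a lower bound. The files name no genome build, so genes are given by symbol without position.

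Signals were taken as log2(signal + 16), which understates the fold changes of dim genes. The 57 control probe sets were left out, and the probe sets above the 40th percentile of mean log2 signal over the 12 arrays were kept, 18625 in all. A probe set was given a gene when the array annotation lists exactly 1 symbol (20826 probe sets). A further 436 list several and 9780 list none. Symbols were checked by Entrez number against the current rat annotation (20764 matched, 0 changed). A gene is represented by its brightest kept probe set, which gives 9906 genes.

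The 6 groups of 2 arrays were taken from the labels and fitted in 1 model with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), so that all groups share 1 estimate of the spread (6 residual degrees of freedom, prior 7.50). The contrasts were each stimulus against its own basal arrays, their average, thrombin response minus TRAP response, TRAP after PTX response minus TRAP response (the PTX effect), and an F test among the basal groups. Tests are 2-sided with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. An array left alone in its group after leaving out its replicate is assumed to vary like the other groups.

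Before the data were examined, the groups, contrasts, settings, alternatives, gene lists and the rule for named genes were fixed. There were 28 lists with 583 genes, and the 25 with at least 5 kept members were tested with camera (correlation 0.01), then with an estimated correlation and with fry, adjusted over the lists within a contrast. Those described here cover immediate-early transcription factors, feedback regulators of MAP kinase and G protein signalling, cyclic AMP and CREB targets, actin cytoskeleton genes regulated by SRF and MRTF, contractile markers, growth factors, haemostasis and matrix remodelling, cytokines, NF-kB feedback, interferon-stimulated genes, targets of BMP, TGF-beta and Notch, growth arrest and FoxO targets, G1 regulators, S and M phase, ribosome biogenesis, respiratory chain subunits, hypoxia and glycolysis, cholesterol, the unfolded protein response, heat shock, collagens, reference genes, and markers of endothelial, leukocyte, adipocyte, fibroblast and Schwann cells. Some genes stand in several lists. The text gives counts of members called over all probe sets and adjusted over the list alone.

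Named genes are, per contrast, the 12 with the largest rise and the 8 with the largest fall among those past the threshold. In a single response both stimulated arrays had to lie beyond both basal arrays, and in the average all 3 experiments had to move the same way. Up to 4 members per list with the smallest p in the average and the receptors F2r, F2rl1, F2rl2 and F2rl3 were added. Genes that fall outside this rule, such as further list members, genes that separate the sets of arrays, genes that differ between basal groups and Ahrr, were chosen after their values were seen. Other targets of the aryl hydrocarbon receptor were listed after Tiparp and Ahrr were seen and before their own values were.

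On simulated data with known changes, the thrombin contrast recovered 85.5% of 2-fold and 100% of 4-fold changes, the average 98% and 100%, and the thrombin minus TRAP contrast 53% and 97%. Of the calls, 5.12%, 7.54% and 3.70% were of probe sets counted as unchanged. A list was also shifted as a whole in the TRAP experiment. The 7.54% of the average may include its members, which were counted as unchanged there. In the TRAP response this list ranked 1 of 25. The PTX contrast held this shift as a true difference and called no probe set. The simulated noise was independent and held no sets of arrays like those found in the data, so it does not measure false calls of the PTX effect.

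The alternatives were other pseudocounts, filters and scalings, no intensity trend, array weights, blocks by replicate number, fits of the compared arrays alone, all 6 basal arrays as the control, stimulated arrays compared directly, a further 2-fold threshold, other list tests, and each array left out in turn. A block for the 2 sets of arrays, a fit without the stimulated arrays outside the set of their own basal arrays (TRAP replicate 1 and TRAP after PTX replicate 1) and a crossed replicate block were chosen after seeing the data.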

Results

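Transcript levels were measured in primary cultures of aortic smooth muscle cells from newborn rats, kept overnight without serum and then stimulated through receptors for thrombin. The 12 arrays form 6 groups of 2: unstimulated cells and cells stimulated for 120 min in each of 3 experiments. The stimuli were thrombin at 2 U/ml, the thrombin receptor-activating peptide TRAP at 25 µM, and TRAP at 25 µM after 24 h with pertussis toxin (PTX) at 200 ng/ml. Thrombin is a protease of blood clotting that cuts its receptors open, TRAP activates such a receptor without the protease, and PTX uncouples receptors from G proteins of the Gi family. The study asks, by its title and design, what these stimuli do to transcription over a short time and how much of it needs Gi. The unstimulated arrays named for the TRAP after PTX experiment carry the label of no agent, so whether those cells had PTX is not stated. If they had none, changes after PTX and TRAP may also hold the effect of PTX itself. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples.

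The median signal of an array lay between 39.5 and 53.4, and the mean without the 2% lowest and highest values was about 200 on every array (200.066 to 200.076). Replicate arrays correlated with r from 0.983 to 0.991 over the tested probe sets. Arrays of the thrombin experiment correlated with those of the other experiments with r from 0.913 to 0.941, and arrays within the TRAP experiments with r from 0.972 to 0.991. The 3'/5' signal ratios, a sign of RNA quality, ran from 1.06 to 1.18 for GAPDH and from 1.28 to 1.504 for actin. The number of arrays, 2 per group, limits the precision: the median standard error of a stimulated response was 0.14 on the log2 scale.

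Signals of smooth muscle genes and thrombin receptors describe the cells, but probe sets differ in brightness, so levels of different genes cannot be ranked by them, and detection calls were not used. Mean signals over the 12 arrays were 7220.5 for Acta2, 5561.3 for Tagln and 1668.2 for Cnn1, all parts of the contractile apparatus. Other contractile markers were dimmer, with Mylk at 88.3, Myh11 at 50.7 and Des at 28.85. F2r, which encodes the main thrombin receptor PAR1, had a mean signal of 3407.1, and F2rl1, which encodes PAR2, had 114.9. F2rl2 at 16.3 and F2rl3 at 6.33 were dimmer than the probe sets that were tested. F2r rose by 0.56 ± 0.09 (SE, log2) after PTX and TRAP (adjusted p = 0.00574), and its changes with thrombin (0.10) and TRAP (0.12) did not pass the test. F2rl1 rose by 0.41 in the average of the 3 responses (adjusted p = 0.0446), a call lost in 9 of the fits that leave out an array (adjusted p between 0.0718 and 0.123). Among markers of other cell types, 3 endothelial, 3 leukocyte and 3 adipocyte genes were bright enough to test, too few for a list test. Of the adventitial fibroblast markers 7 were kept, with Mfap5 at 5431.3, Gsn at 1329.6 and Pdgfra at 239, and of the Schwann cell and neural markers 5, with Cnp the brightest at 256.

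The 8 arrays of the TRAP experiments did not group by their labels alone. In the acute-phase gene Saa3 the signal was 15.9 to 22.8 on both basal TRAP arrays, TRAP replicate 2 and TRAP after PTX replicate 1. It was 222.5 to 420.9 on both basal arrays of the PTX experiment, TRAP replicate 1 and TRAP after PTX replicate 2. Lcn2, C3, Pla2g2a and Lbp, further genes of inflammation, split the same way, with Lcn2 at 20.2 to 32.8 against 275.2 to 360.2. The chemokine Ccl2 was at 598.4 to 1590.9 on the first set of 4 arrays and at 3396.6 to 6720.7 on the second. Genes of cell division went the other way, with Mki67 at 900.3 to 1095.7 on the first set and 515.4 to 607.5 on the second. These 2 sets of arrays were found in the data and are not groups of the study, and their effect is given beside the gene groups that move most with them. Low adjusted p from limma fits that use these sets are therefore not independent support.

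**Figure D1:**
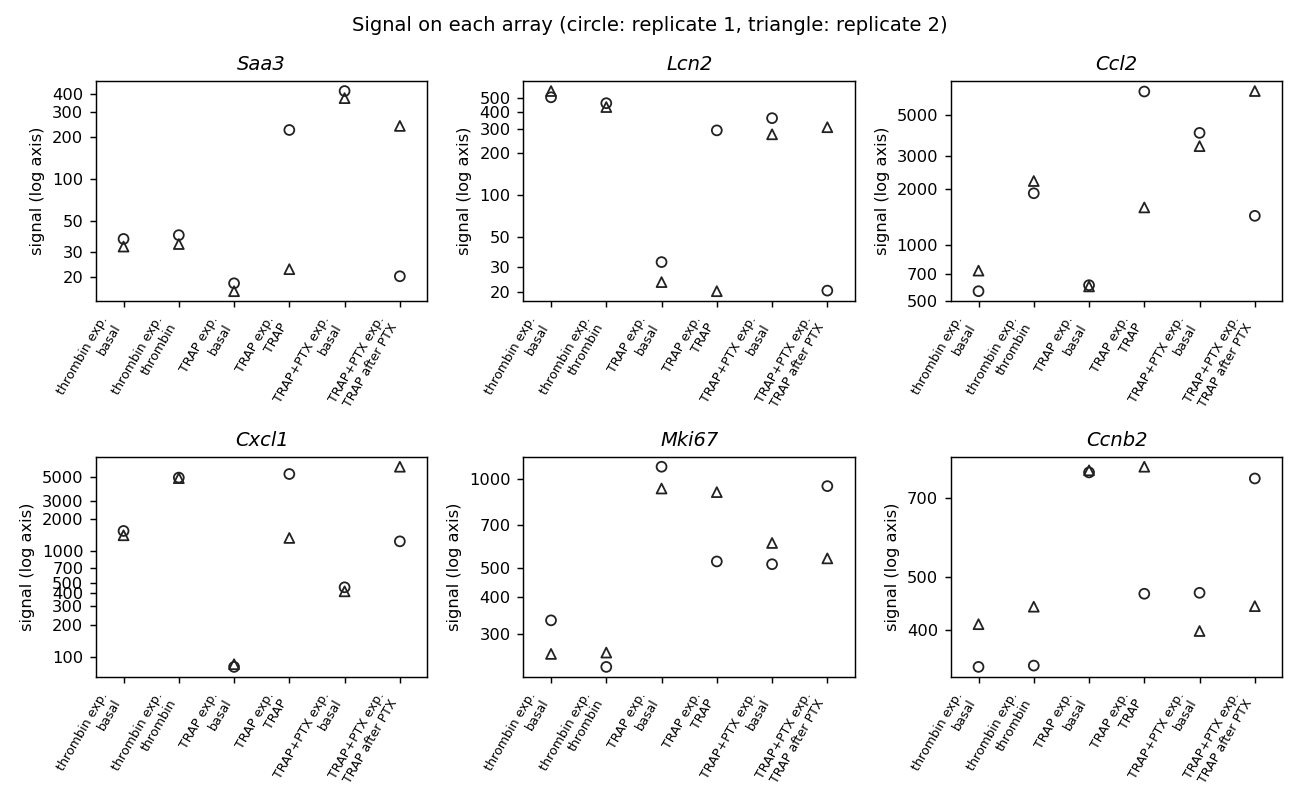
Signal (log axis) of 6 genes on each of the 12 arrays, with a circle for replicate 1 and a triangle for replicate 2 of each group. In Saa3, TRAP replicate 1 and TRAP after PTX replicate 2 sit with the basal arrays of the PTX experiment (222.5 to 420.9), and the other stimulated arrays of the TRAP experiments sit with the basal TRAP arrays (15.9 to 22.8).

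Thrombin was compared with unstimulated cells of the same experiment to find what the protease itself does. Serpinb2, an inhibitor of plasminogen activators, rose from a signal of 37.35 ± 10.4 to 1426 ± 148 (SD, n = 2), a log2 change of 4.77 ± 0.47 (SE). The transcription factor genes Fosl1 (3.78 ± 0.25), Egr2 (3.09 ± 0.20), Nr4a1 (2.61 ± 0.24) and Fosb (2.54 ± 0.33) rose with it. So did Ptgs2, the inducible cyclooxygenase (3.03 ± 0.12), Dusp5, a phosphatase that inactivates ERK (2.85 ± 0.31), Sphk1, a sphingosine kinase (2.74 ± 0.25), and Arc (2.74 ± 0.22). Bambi, a decoy receptor of BMP and TGF-beta signalling, fell from 836.7 ± 76.9 to 99.75 ± 34.0, a log2 change of -2.91 ± 0.17. Spry1, an inhibitor of receptor kinase signalling (-1.28 ± 0.14), Ppp1r3b, a glycogen-targeting subunit of a phosphatase (-1.44 ± 0.17), and the heart and limb factor Tbx5 (-1.29 ± 0.16) fell too. In limma's test with Benjamini-Hochberg adjustment, 490 of 18625 probe sets rose and 392 fell, 179 of them by at least 2-fold. The adjusted p was 5.82e-05 for Serpinb2, 1.65e-08 for Ptgs2 and 5.34e-07 for Bambi. With each array centred on its median, the split was 608 up and 261 down. The total of 882 was 409 without basal replicate 1, 342 without thrombin replicate 1 and 357 without thrombin replicate 2.

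Among the gene lists, immediate-early transcription factors moved most with thrombin: 19 of 32 measured members rose and none fell, with a median of 0.87 (camera adjusted p = 2.98e-31). Adjusted over the list alone, 22 rose and 1 fell. Feedback regulators of MAP kinase and G protein signalling followed (10 of 19 rose and 2 fell; adjusted over the list alone, 13 and 2), among them Errfi1 (2.15), Rgs16 (2.11) and Sgk1 (2.32). Of 16 targets of cyclic AMP and CREB, 7 rose and 1 fell (9 and 1 adjusted over the list alone), with Per2, a clock gene, up by 0.87. Actin cytoskeleton genes regulated by SRF and MRTF rose in 7 of 21 members (11 adjusted over the list alone), including Ankrd1 (0.62), Enah (0.49) and Zyx (0.43). Growth factors and secreted ligands rose in 5 of 23 and fell in 1 (5 and 1 adjusted over the list alone), with Hbegf, a ligand of the EGF receptor, up by 1.98 ± 0.12, and the vasoconstrictor gene Edn1 by 1.33. Haemostasis, protease and matrix remodelling genes rose in 4 of 18 (8 adjusted over the list alone), with the urokinase receptor Plaur up by 2.32 ± 0.16 and tissue factor, F3, by 1.25. Growth arrest and FoxO target genes fell in 7 of 20 (8 adjusted over the list alone), among them Foxo3 (-1.01), Sesn1 (-1.09), Ccng2 (-0.98) and the cell cycle inhibitor Cdkn1b (-0.73). Each of these 7 lists was also called with an estimated correlation, with adjusted p from 0.00841 to 0.0381.

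A further 5 lists were called after thrombin with the preset correlation alone. Cytokines, chemokines and adhesion molecules rose in 4 of 14 (6 adjusted over the list alone; adjusted p = 0.163 with an estimated correlation), NF-kB feedback genes in 4 of 17 (adjusted over the list alone, 6 rose and 2 fell; adjusted p = 0.386 with an estimated correlation) and heat shock genes in 2 of 13 (4 adjusted over the list alone; adjusted p = 0.264 with an estimated correlation). Contractile smooth muscle markers rose in 2 of 19 (7 adjusted over the list alone; adjusted p = 0.103 with an estimated correlation), with Cnn1 up by 0.63 and Csrp1 by 0.35. Cholesterol genes rose in 2 of 14 (2 adjusted over the list alone; adjusted p = 0.407 with an estimated correlation), namely Msmo1 (0.69) and Insig1 (0.49). The chemokines Cxcl1 (1.72), Ccl2 (1.65) and Ccl7 (1.47) did not pass (adjusted p = 0.131, 0.149 and 0.279), and passed at the same folds with the array sets as a block (adjusted p = 3.08e-07, 4.17e-06 and 2.47e-06). The TRAP groups, whose arrays lie in both sets, widen the spread shared by all groups. The block was read from these same arrays and these chemokines differ between its sets, so its p-values are not independent support for calls after thrombin.

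TRAP was compared with its own unstimulated arrays to see what activating the receptor without the protease does. The chemokine gene Cxcl1 rose by 4.77 ± 0.60 (SE, log2), or by 3.77 without the stimulated arrays outside the set of their own basal arrays and 3.69 with the sets as a block. Fosl1 rose by 3.49 ± 0.25 and Nfkbiz, a regulator of NF-kB, by 2.69 ± 0.36, or by 2.09 without those arrays and 2.08 with the block. Noct, a circadian phosphatase gene, rose by 2.51 ± 0.19, Dusp6 by 2.06 ± 0.14, Cebpd, a factor of the inflammatory response, by 1.99 ± 0.23, Egr1 by 1.99 ± 0.11 and Plaur by 1.94 ± 0.16. Id2, an inhibitor of helix-loop-helix factors, fell by 1.95 ± 0.18, Bambi by 1.44 ± 0.17, Arid5b by 1.36 ± 0.15 and Kcne4, a potassium channel subunit, by 1.27 ± 0.19. The stress genes Trib3 (-1.46 ± 0.20) and Chac1 (-1.27 ± 0.14) fell as well. In limma's test 342 probe sets rose and 385 fell, 170 of them by at least 2-fold, and median centring gave 434 up and 263 down. The adjusted p was 3.53e-06 for Fosl1, 5.14e-07 for Egr1 and 3.38e-05 for Id2. The total of 727 was 208 and 246 without basal replicate 1 and 2, and 442 and 348 without TRAP replicate 1 and 2. Dusp5 (1.92) lost its call without basal replicate 1 (1.72, adjusted p = 0.0567). The chemokine Ccl2, which rose by 2.41 ± 0.59, lost its call in 9 of the 12 fits that leave out an array, with adjusted p between 0.0524 and 0.287, and measured 1.38 without TRAP replicate 1. It passed at 1.34 with the array sets as a block (adjusted p = 0.000119) and at 1.38 without the stimulated arrays outside the set of their own basal arrays (adjusted p = 0.000746).

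After TRAP, 16 of 32 immediate-early factors rose and none fell (21 and 1 adjusted over the list alone), with a median of 0.60. This was the only one of 12 called lists that was also called with an estimated correlation (adjusted p = 0.0311). Cytokines, chemokines and adhesion molecules rose in 6 of 14 (11 adjusted over the list alone; adjusted p = 0.0534 with an estimated correlation) and NF-kB feedback genes in 6 of 17 (8 adjusted over the list alone; adjusted p = 0.106 with an estimated correlation), such as Tnfaip3 (1.86) and Irf1 (1.17). The cytokine list moves with the 2 sets of arrays, with a median of 1.28 with all arrays and 0.87 without the stimulated arrays outside the set of their own basal arrays. The median of the NF-kB list was 0.47 and 0.42, and that of the haemostasis list 0.17 and 0.07. The feedback regulators rose in 6 of 19 (8 adjusted over the list alone; adjusted p = 0.101 with an estimated correlation), CREB targets in 4 of 16 (5; adjusted p = 0.106 with an estimated correlation), haemostasis and protease genes in 4 of 18 (5; adjusted p = 0.0534 with an estimated correlation) and heat shock genes in 3 of 13 (6; adjusted p = 0.158 with an estimated correlation). Growth factors rose in 2 of 23 (adjusted over the list alone, 3 rose and 1 fell; adjusted p = 0.106 with an estimated correlation) and collagen genes in 2 of 19 (2; adjusted p = 0.471 with an estimated correlation). None of 21 actin cytoskeleton genes passed the test 1 by 1 (2 rose adjusted over the list alone), while the list was called upward with a median of 0.09 (adjusted p = 0.106 with an estimated correlation). Growth arrest genes fell in 2 of 20 (adjusted over the list alone, 1 rose and 6 fell; adjusted p = 0.106 with an estimated correlation), Klf15 by 1.24 ± 0.21. The S and M phase list was called downward with a median of -0.31 and no member past the threshold on its own, over all genes or adjusted over the list alone (adjusted p = 0.583 with an estimated correlation). It moves with the 2 sets of arrays and measured -0.05 without the stimulated arrays outside the set of their own basal arrays (adjusted p = 0.53).

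TRAP after PTX was compared with the unstimulated arrays of the same experiment, whose cells may not have had PTX. The changes may therefore be of PTX itself as well as of the peptide once Gi is uncoupled. Fosl1 rose by 3.17 ± 0.25 (SE, log2), Noct by 2.44 ± 0.19, Akap12, a scaffold of protein kinase A, by 2.42 ± 0.34, Egr1 by 2.38 ± 0.11 and Sgk1 by 2.25 ± 0.28. The cytokine gene Tslp rose by 1.99 ± 0.17, Egr2 by 1.94 ± 0.20, Dusp6 by 1.92 ± 0.14 and Plaur by 1.72 ± 0.16. Bambi fell by 1.87 ± 0.17, Klf15 by 1.83 ± 0.21, Trib3 by 1.44 ± 0.20, Kcne4 by 1.402 ± 0.19 and Chac1 by 1.24 ± 0.14. In limma's test 313 probe sets rose and 192 fell, 127 of them by at least 2-fold, and median centring gave 412 up and 127 down. The adjusted p was 9.92e-08 for Egr1, 1.18e-05 for Fosl1 and 4.53e-05 for Bambi. The total of 505 was 191 without basal replicate 2, 149 and 292 without TRAP after PTX replicate 1 and 2, and 166 without the stimulated arrays outside the set of their own basal arrays. Cxcl1, which rose by 2.64 ± 0.60, moves with the array sets: it lost its call in 5 of the fits that leave out an array (adjusted p between 0.0529 and 0.177) and measured 1.47 without TRAP after PTX replicate 2. With the sets as a block it rose by 3.72 (adjusted p = 1.48e-09), and without the stimulated arrays outside the set of their own basal arrays by 3.80 (adjusted p = 1.62e-08). Rasl12 (-1.89) lost its call without basal replicate 1 (-1.62, adjusted p = 0.0506) or TRAP after PTX replicate 1 (-1.49, adjusted p = 0.0669).

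After PTX and TRAP, 14 of 32 immediate-early factors rose and none fell (22 and 2 adjusted over the list alone), with a median of 0.54. This was again the only 1 of 11 called lists that was called with an estimated correlation (adjusted p = 0.0324). Feedback regulators rose in 7 of 19 (9 adjusted over the list alone; adjusted p = 0.0947 with an estimated correlation), CREB targets in 4 of 16 (adjusted over the list alone, 7 rose and 1 fell; adjusted p = 0.0947 with an estimated correlation) and actin cytoskeleton genes in 3 of 21 (4; adjusted p = 0.0566 with an estimated correlation). Heat shock genes rose in 2 of 13 (7; adjusted p = 0.161 with an estimated correlation), haemostasis genes in 3 of 18 (adjusted over the list alone, 5 rose and 2 fell; adjusted p = 0.161 with an estimated correlation) and growth factors in 1 of 23 (4; adjusted p = 0.0947 with an estimated correlation). Cytokines rose in 3 of 14 (adjusted over the list alone, 3 rose and 1 fell; adjusted p = 0.345 with an estimated correlation) and NF-kB genes in 2 of 17 (3; adjusted p = 0.342 with an estimated correlation). Their medians of 0.18 and 0.34 were 0.69 and 0.54 without the stimulated arrays outside the set of their own basal arrays, and that of the haemostasis list went from 0.07 to 0.21. The S and M phase list was called upward with a median of 0.23 and no member past the threshold, over all genes or adjusted over the list alone (adjusted p = 0.541 with an estimated correlation). Without those arrays it measured -0.10 (adjusted p = 0.453). The list of constitutive reference genes was called upward with a median of 0.12 and none of 11 members past the threshold, over all genes or adjusted over the list alone (adjusted p = 0.504 with an estimated correlation). The number of called lists was 6 without TRAP after PTX replicate 2.

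The average of the 3 responses, 6 stimulated against 6 basal arrays within their experiments, gives the most precise view of what stimulation does. Fosl1 rose by 3.48 ± 0.14 (SE, log2), Cxcl1 by 3.04 ± 0.34, Serpinb2 by 2.79 ± 0.27, Noct by 2.59 ± 0.11, Egr2 by 2.24 ± 0.12 and Ptgs2 by 2.01 ± 0.07. Plaur rose by 2.00 ± 0.09, Egr1 by 1.99 ± 0.06, Hbegf by 1.58 ± 0.07 and tissue factor, F3, by 0.98. Bambi fell by 2.07 ± 0.10, Klf15, a factor of metabolic genes, by 1.38 ± 0.12, Id2 by 1.20 ± 0.10, Tent5c by 1.11 ± 0.13 and Lurap1l by 1.02 ± 0.07. In limma's test 1034 probe sets rose and 1419 fell, and 94 changed by at least 2-fold. The adjusted p was 3.85e-09 for Fosl1, 3.67e-10 for Egr1 and 1.2e-08 for Bambi. The direction of the many small changes depends on scaling, with 1456 up and 794 down after median centring and 1140 up and 1033 down after quantile normalization. The total of 2453 was 1628 without basal TRAP replicate 1.

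**Figure D2:**
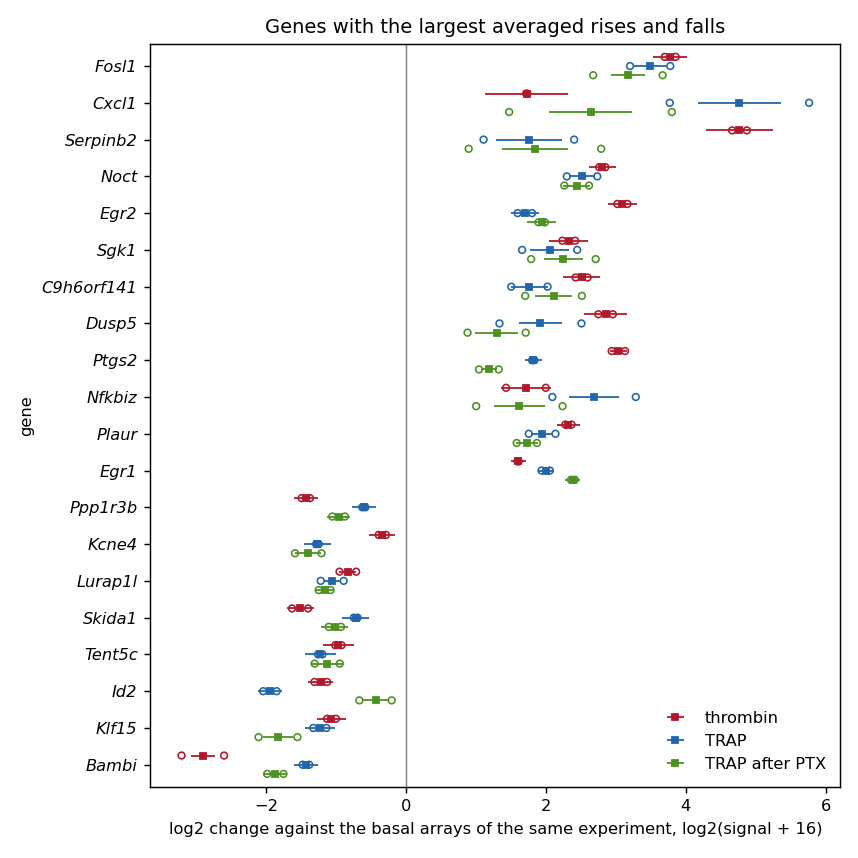
Log2 change of the 20 genes with the largest averaged rises and falls, in each experiment against its own basal arrays. Squares with bars are fitted changes with their standard errors, open circles single stimulated arrays against the mean of the basal arrays. Fosl1 rose by 3.17 to 3.78 and Bambi fell in all 3 experiments.

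Averaged over the experiments, 11 of the 25 tested lists were called, and 7 of them also with an estimated correlation (adjusted p from 0.011 to 0.0402). Of 32 immediate-early factors, 25 rose and 1 fell (27 and 1 adjusted over the list alone), with Ier2 up by 1.63 and Zfp36, which destabilises cytokine mRNA, by 1.25. Feedback regulators rose in 11 of 19 and fell in 1 (12 and 1 adjusted over the list alone), CREB targets rose in 8 of 16 (adjusted over the list alone, 9 rose and 1 fell), and SRF and MRTF genes in 9 of 21 (15 adjusted over the list alone). Haemostasis and protease genes rose in 7 of 18 (9 adjusted over the list alone), Adamts1 by 0.64 and Timp1 by 0.36. Growth factors rose in 5 of 23 and fell in 1 (5 and 2 adjusted over the list alone), Areg by 1.22 and Inhba by 0.46. Growth arrest genes fell in 8 of 20 (adjusted over the list alone, 1 rose and 8 fell). With the preset correlation alone, 4 more lists were called upward. Cytokines rose in 9 of 14 (10 adjusted over the list alone; adjusted p = 0.0634 with an estimated correlation) and NF-kB genes rose in 9 of 17 and fell in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). Heat shock genes rose in 6 of 13 (7 adjusted over the list alone; adjusted p = 0.123 with an estimated correlation), Dnajb1 by 0.60 and Hspa1a by 0.59. Contractile markers rose in 2 of 19 (2 adjusted over the list alone; adjusted p = 0.237 with an estimated correlation).

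**Figure D3:**
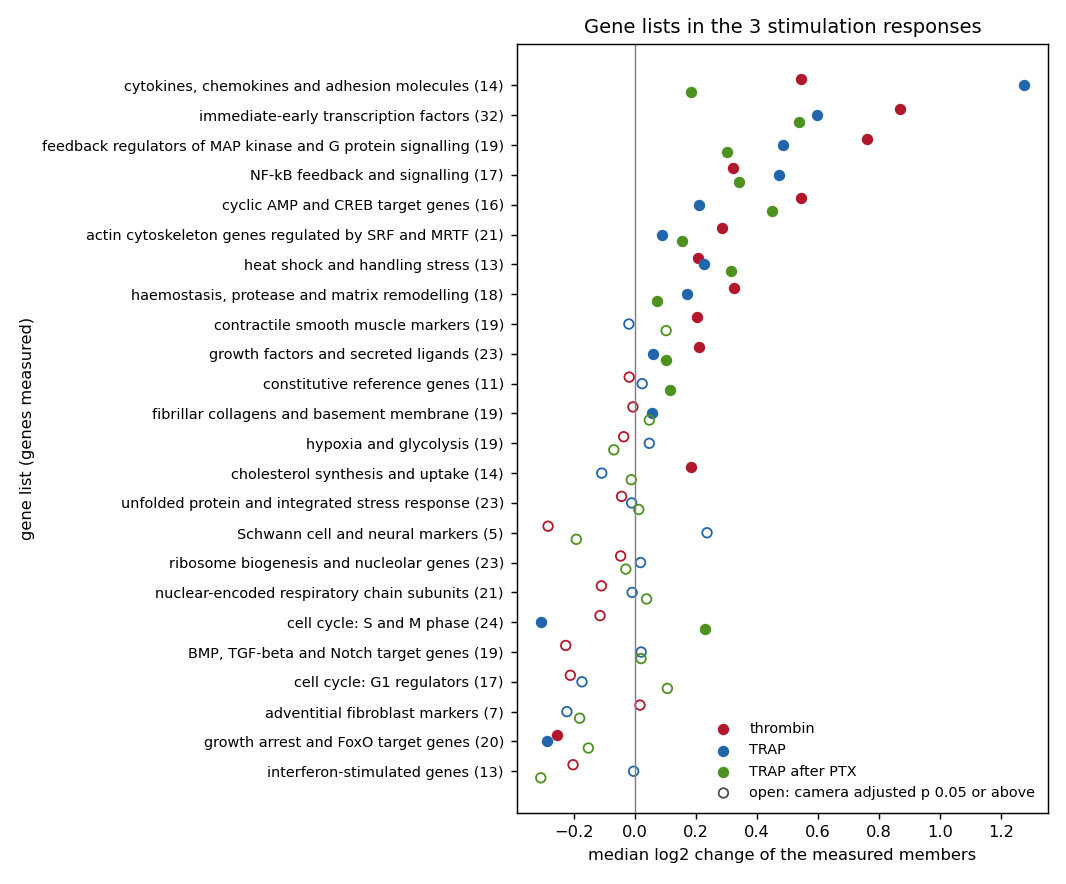
Median log2 change of the measured members of the gene lists described here, in the 3 responses, with filled points for lists with a camera adjusted p under 0.05. Immediate-early transcription factors moved upward in all 3 responses, with medians of 0.87, 0.60 and 0.54.

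Several lists without a call in the averaged contrast held genes that moved apart. Among 19 targets of BMP, TGF-beta and Notch, 6 rose and 7 fell (7 and 8 adjusted over the list alone): Id3 rose by 1.42 and Tgif1 by 0.71, while Id2 and Bambi fell. Among 23 genes of the unfolded protein and integrated stress response, 2 rose and 5 fell (2 and 5 adjusted over the list alone), with Sesn2 at -0.80 and Ppp1r15a at 0.52. In the cholesterol list 3 rose and 4 fell (3 and 4 adjusted over the list alone). Among G1 regulators 2 rose and 3 fell (2 and 6 adjusted over the list alone), with Gadd45g up by 0.50 and Gadd45a down (-0.43). Hypoxia and glycolysis genes gave 2 up and 1 down of 19 (2 and 1 adjusted over the list alone), Adm by 0.58 and Hk2 by 0.48. Interferon-stimulated genes gave 1 up and 2 down of 13 (1 and 5 adjusted over the list alone), with Irf9 at -0.45 and Usp18 at 0.62. In the remaining lists at most 2 members moved: ribosome biogenesis (1 up of 23), respiratory chain subunits (1 down of 21), adventitial fibroblast markers (1 down of 7) and Schwann cell markers (1 up and 1 down of 5). None of 24 S and M phase genes, 19 collagen genes or 11 reference genes passed limma's test in this contrast. Adjusted over the list alone, the counts in these 7 lists were 1 down for fibroblast markers, 1 up and 1 down for Schwann cell markers and 0 for the others. The camera adjusted p of these lists was 0.115 or more. Of the untested lists, the endothelial gene Flt1 rose by 1.39 ± 0.15, and no leukocyte or adipocyte marker passed.

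The 3 responses were set against each other, since each has its own basal arrays. Over all tested probe sets the log2 changes of thrombin and TRAP correlated across genes with r = 0.399, those of thrombin and TRAP after PTX with r = 0.370, and those of both TRAP responses with r = 0.413. Genes are not independent replicates, so no p is given. Both thrombin and TRAP raised 162 probe sets, where independent lists would share 9.0, and lowered 54, where independent lists would share 8.1. In 8 probe sets the calls were opposite. In all 3 experiments 106 probe sets of 77 named genes rose, among them Fosl1, Egr1, Hbegf, Plaur, Ptgs2, Dusp6 and Tnfaip3, and 27 probe sets of 23 named genes fell, among them Bambi, Klf15, Tbx5 and Tcf4.

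**Figure D4:**
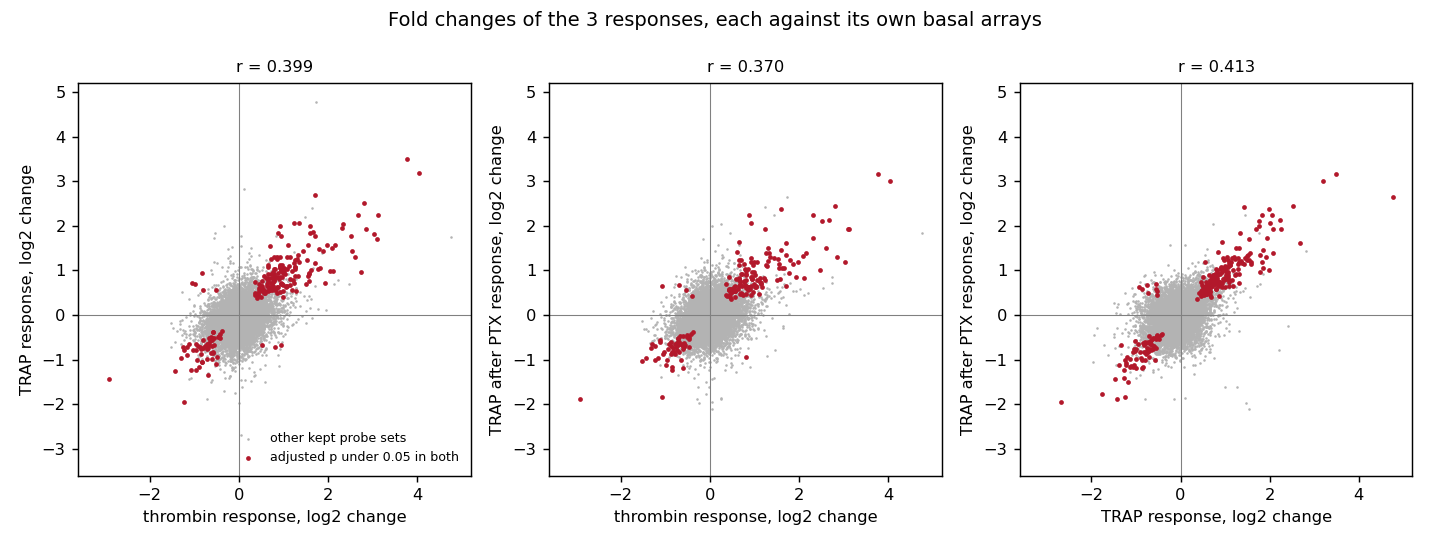
Log2 changes of all tested probe sets, 1 panel for each pair of responses, with red points for probe sets with an adjusted p under 0.05 in both. The correlations across genes are 0.399, 0.370 and 0.413.

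The probe sets called after thrombin were followed into the TRAP experiments, which share no arrays with the thrombin experiment. The median change of these 882 probe sets in the thrombin direction was 0.73 with thrombin, 0.28 with TRAP and 0.30 with TRAP after PTX. The direction was the same as with thrombin in 83.8% of them with TRAP and in 84.2% with TRAP after PTX. The medians of single stimulated arrays were 0.26 and 0.31 with TRAP and 0.33 and 0.26 with TRAP after PTX, so these values differed by less than the spread between replicates. The thrombin value is raised by having chosen the probe sets there, and no test was made of this measure. Leaving out thrombin replicate 1, which leaves fewer probe sets called, gave 0.46 with TRAP, and leaving out basal thrombin replicate 2 gave 0.17 with TRAP after PTX.

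The difference between the thrombin and TRAP responses was tested directly. The 2 stimuli were given in separate experiments, whose unstimulated arrays differed in 7584 of 18625 probe sets. Differences below may therefore reflect the cells of each experiment as well as protease or peptide, which this design cannot tell apart. Several transcription and growth genes were higher with thrombin: Klf6 differed by 1.65 ± 0.21 (SE, log2), Myc by 1.43 ± 0.16, Klf7 by 1.52 ± 0.23 and Ptgs2 by 1.22 ± 0.17. Myc rose by 1.08 with thrombin, and its change of -0.35 with TRAP did not pass the test. Chac1 (1.62 ± 0.20), Trib3 (1.51 ± 0.28), Sesn2 (1.09 ± 0.20) and Arid5b (1.70 ± 0.21) fell with TRAP, did not pass with thrombin, and differed. The first 3 belong to the unfolded protein and integrated stress list, of which 4 of 23 members were higher (4 adjusted over the list alone) while the list was not called (adjusted p = 0.119, and 0.549 with an estimated correlation). It was called higher with the array sets as a block (median 0.09, adjusted p = 0.00574). In the other direction, Cebpd (-2.33 ± 0.32), Tslp (-1.71 ± 0.24), Irf1 (-1.66 ± 0.20), Il15 (-1.77 ± 0.18) and Tiparp (-1.69 ± 0.14) were higher with TRAP. In limma's test of the difference 60 probe sets were higher with thrombin and 39 lower, 69 of them by at least 2-fold, with adjusted p of 0.00328 for Klf6, 0.00506 for Cebpd and 0.000207 for Tiparp. The total of 99 was 60 without basal thrombin replicate 1, 37 and 33 without basal TRAP replicate 1 and 2, and 33 and 39 without thrombin replicate 1 and 2. Klf7 lost its call without basal TRAP replicate 2 (adjusted p = 0.0584) or thrombin replicate 2 (adjusted p = 0.0589), and Trib3 in 5 of the fits that leave out an array (adjusted p between 0.0909 and 0.136).

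**Figure D5:**
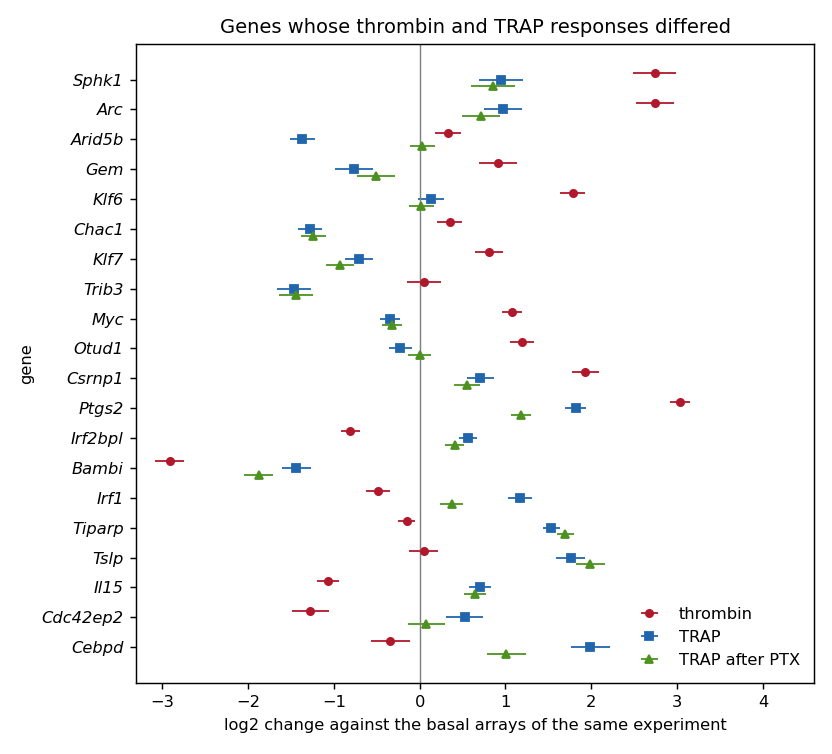
Log2 change (points) with its standard error (bars) in each experiment for the 20 genes whose thrombin and TRAP responses differed most. Myc, Klf6 and Ptgs2 sit farther right with thrombin, and Cebpd, Tslp and Tiparp with TRAP.

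Of the lists, 8 were called in this difference and none with an estimated correlation (lowest adjusted p = 0.165), and fry's rotation test called 1, the growth arrest list, which is not among the 8. Immediate-early factors (median 0.27), SRF and MRTF genes (0.15), contractile markers (0.23), cholesterol genes (0.19), CREB targets (0.20) and S and M phase genes (0.28) were higher with thrombin. Cytokines (-0.53) and NF-kB genes (-0.31) were lower. Without the stimulated arrays outside the set of their own basal arrays, the cytokine, NF-kB and S and M phase medians were -0.15, -0.11 and 0.01, with adjusted p of 0.294, 0.45 and 0.928. With the array sets as a block these 3 lists lost their call too (adjusted p = 0.34, 0.371 and 0.745), as did CREB targets (median 0.05, adjusted p = 0.205). The medians of the other 4 shrank: immediate-early factors to -0.01, so that their call gives no common direction, cholesterol genes to 0.08, SRF and MRTF genes to 0.12 and contractile markers to 0.16. Haemostasis genes gained a call with the block (median 0.12, adjusted p = 0.0224; 0.15 and 0.0679 without it), as did the unfolded protein list. Members past the threshold were 4 higher of the immediate-early list (adjusted over the list alone, 10 higher and 1 lower), 1 of the SRF and MRTF list (3 adjusted over the list alone), and in the cytokine list 1 higher and 1 lower (1 and 3 adjusted over the list alone). In the NF-kB list 1 was lower (1 adjusted over the list alone). None passed in the contractile, CREB, cholesterol and S and M phase lists over all genes; adjusted over the list alone, 4 cholesterol genes were higher and 2 CREB targets were higher and 1 lower.

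The effect of PTX on the TRAP response was tested as the difference between both TRAP responses, each against its own basal arrays. It may hold the effect of PTX itself if the basal arrays of the PTX experiment had none. Several induced genes, and Bambi, which fell, responded with and without PTX, with differences that did not pass the test: Fosl1 differed by -0.32 (95% interval -1.07 to 0.43), Egr1 by 0.39 (0.06 to 0.72), Dusp6 by -0.14 (-0.58 to 0.30), Plaur by -0.22 (-0.71 to 0.27) and Bambi by -0.44 (-0.96 to 0.08). Ptgs2 differed by -0.63 (-0.999 to -0.27; adjusted p = 0.222). Dusp5 differed by -0.63 (adjusted p = 0.777), but by -1.63 with the array sets as a block (adjusted p = 0.0397) and without the stimulated arrays outside the set of their own basal arrays (adjusted p = 0.0583). Fosl1 differed by -1.10 in both of these fits (adjusted p = 0.0898 and 0.111). The basal groups of both TRAP experiments lie wholly in different sets, so both of these fits compare TRAP replicate 2 with TRAP after PTX replicate 2. In them, a response that differs between the sets looks the same as an effect of PTX. The intervals are not adjusted for the number of genes, and the median half-width over genes was 0.43. In limma's test 24 probe sets of 17 named genes differed, and all 24 were higher with PTX. Of their median difference of 1.31, the part from stimulated arrays had a median of 0.70. The part from basal arrays, which were lower in the PTX experiment, had 0.55, and for Nuf2 it was 0.93 against 0.43. The 24 include Id2 (1.51 ± 0.25, SE), Herc1, a ubiquitin ligase (1.44 ± 0.22), Arid5b (1.398 ± 0.21), Nuf2, a kinetochore protein (1.36 ± 0.23), and the transcription factor Nfix (1.19 ± 0.16), with adjusted p from 0.0158 to 0.0386. Each of these 5 lost its call in 5 to 10 of the fits that leave out an array, with adjusted p up to 0.218. With the array sets as a block, Id2 (1.38 ± 0.30, adjusted p = 0.14), Arid5b (1.34 ± 0.26, adjusted p = 0.0968) and Nuf2 (0.97 ± 0.22, adjusted p = 0.145) lost their call. Herc1 (1.62 ± 0.26, adjusted p = 0.0377) and Nfix (1.36 ± 0.18, adjusted p = 0.0333) passed. Without the stimulated arrays outside the set of their own basal arrays Herc1 lost its call (adjusted p = 0.0583), and of 9 genes whose brightest probe set is among the 24 only Nfix and Nipbl kept it (adjusted p = 0.0342 for both). Of the 24, 21 fell with TRAP and 11 rose with TRAP after PTX. The count was 0 without basal TRAP replicate 1, basal replicate 2 of the PTX experiment, TRAP replicate 2 or TRAP after PTX replicate 1, 1 without basal TRAP replicate 2, 11 without either stimulated thrombin array and 47 without TRAP replicate 1. The probe sets with an unadjusted p under 0.05 were 1542. Without the stimulated arrays outside the set of their own basal arrays 9 probe sets were called, 6 of them among the 24.

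Gene lists in the PTX effect moved with the array sets. Cytokines (median -0.85) and NF-kB genes (-0.39) were called lower with PTX, and S and M phase genes (0.51) and cholesterol genes (0.12) higher, while no member passed limma's test over all genes. Adjusted over the list alone, 7 cytokine and 2 NF-kB genes were lower, and no S and M phase or cholesterol gene passed. None of the 4 was called with an estimated correlation (lowest adjusted p = 0.413) or by fry. Without the stimulated arrays outside the set of their own basal arrays, the medians were -0.15 for cytokines, 0.03 for NF-kB genes, -0.02 for S and M phase genes and 0.02 for cholesterol genes, with adjusted p of 0.194, 0.428, 0.963 and 0.963. Among the cytokines, Cxcl1 differed by -2.13 with all arrays and by 0.03 without them, and Ccl2 by -2.65 and -0.51. With the array sets as a block, 3 other lists were called: feedback regulators (median -0.33, adjusted p = 0.00945) and immediate-early factors (-0.15, 0.0156) lower with PTX, and the unfolded protein list higher (0.07, 0.0114). In the fit of all arrays without a block these medians were 0.06, -0.03 and 0.01, with adjusted p of 0.947, 0.947 and 0.921. With the block, an effect of PTX cannot be told apart from a response that differs between the sets. The number of called lists ranged from 2 without TRAP after PTX replicate 1 to 7 without basal TRAP replicate 1.

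Unstimulated cells were compared between experiments to measure how alike the starting points were. The basal arrays of the thrombin experiment differed widely from both others: 7862 probe sets (42.2%) differed among the 3 basal groups. Against basal thrombin arrays, basal TRAP arrays were higher in Myh2, a skeletal muscle myosin (5.15 ± 0.13, SE, log2), the cartilage proteoglycan Acan (4.57 ± 0.28), the potassium channel Kcnk2 (4.12 ± 0.10) and the smooth muscle coactivator Myocd (3.68 ± 0.21). They were lower in Cxcl1 (-3.92 ± 0.60), Lcn2 (-3.65 ± 0.86), Prnd (-3.50 ± 0.32) and the metallothionein Mt2A (-2.60 ± 0.24). These examples were chosen as the largest differences after their values were seen. Between basal TRAP and basal TRAP after PTX arrays, 8 probe sets differed: Klhl40 (1.79), Il1rl1 (0.94), Cxcl12 (0.71) and Pcbd2 (0.66) were higher in the PTX experiment, and Max (-1.51), Rab5b (-1.15), Hmmr (-0.89) and Prrc2c (-0.76) were lower. These 8 do not show that the basal groups were otherwise alike. The genes that separate the array sets differed by more, Saa3 by 3.65 ± 0.76, Lcn2 by 2.91 ± 0.86 and Ccl2 by 2.58 ± 0.59. They missed the threshold (adjusted p = 0.102, 0.196 and 0.126) because the spread shared by all groups includes the stimulated TRAP groups, whose arrays lie in both sets. The thrombin and TRAP cells therefore started from different levels, and a comparison of stimulated arrays alone, which ignores this, called 6843 probe sets between thrombin and TRAP. The difference of responses subtracts these levels, but it cannot separate the stimulus from cells that respond differently.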

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

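The tests of the array sets against the labels and of gene length on the called genes were chosen only after the result was seen. So were the fits with the array sets as a block or without 2 arrays.

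The thrombin and TRAP responses differed in 99 probe sets by a test of the difference itself. Stimulus and experiment cannot be told apart in this difference. Higher with thrombin were Sphk1 (1.79), Arc (1.78), Arid5b (1.70), Gem (1.69), Klf6 (1.65), Chac1 (1.62), Klf7 (1.52), Trib3 (1.51), Myc (1.43), Otud1 (1.42), Csrnp1 (1.22) and Ptgs2 (1.22). Lower were Cebpd (-2.33), Cdc42ep2 (-1.80), Il15 (-1.77), Tslp (-1.71), Tiparp (-1.69), Irf1 (-1.66), Bambi (-1.47) and Irf2bpl (-1.37). Without 1 array, calls were lost for Sphk1 (9 arrays, adjusted p up to 0.185), Csrnp1 (7, up to 0.122), Arc (6, up to 0.135), Gem (6, up to 0.148), Trib3 (5, up to 0.136), Cdc42ep2 (4, up to 0.102), Bambi (2, up to 0.0829) and Klf7 (2, up to 0.0589). Ahrr (-1.37) and Cyp1b1 (-1.24) also differed: Ahrr was chosen after its value was seen, and Cyp1b1 came from a list of targets written before its value was seen and was picked from that list afterwards. The list medians that differed were SRF and MRTF genes (0.15), S and M phase (0.28), cholesterol (0.19), contractile markers (0.23), CREB targets (0.20), immediate-early factors (0.27), cytokines (-0.53) and NF-kB genes (-0.31). None of these lists was called with an estimated correlation (lowest adjusted p = 0.165). With the array sets as a block the medians were 0.05 for CREB targets (adjusted p = 0.205), -0.01 for S and M phase (adjusted p = 0.745), -0.15 for cytokines (adjusted p = 0.34) and -0.10 for NF-kB genes (adjusted p = 0.371), which lost their calls. For immediate-early factors, cholesterol, SRF and MRTF genes and contractile markers they were -0.01, 0.08, 0.12 and 0.16.

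The responses to TRAP with and without PTX differed in 24 probe sets of 17 genes with a symbol by the same kind of test. Of these genes 9 had their brightest probe set among the 24 and so could be named: Id2 (1.51), Herc1 (1.44), Arid5b (1.398), Nuf2 (1.36), Nfix (1.19), Ubn1 (1.12), Nipbl (1.01), Loxl2 (0.97) and Srrm2 (0.97). Each lost its call without at least 5 of the arrays, 1 at a time. Ubn1, Nipbl, Loxl2 and Srrm2 each have 1 other probe set of the opposite sign. The list medians were 0.51 for S and M phase, 0.12 for cholesterol, -0.85 for cytokines and -0.39 for NF-kB genes, with no call at an estimated correlation (lowest adjusted p = 0.413).

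The 8 arrays of the TRAP experiments fall into 2 sets of 4 that cut across the labels. Arrays of 1 stimulated label differed by at least 2.77 (log2) in the acute-phase median, which argues against the toxin acting as labelled as the whole cause. An exchange of the labels of TRAP replicate 1 and TRAP after PTX replicate 1 would place each group within 1 set. The label split of the 4 stimulated arrays separated 18 probe sets by 2-fold in pair means, the split by replicate number 7 and the remaining split 51. Other definitions gave 1, 0 and 24, and 301, 85 and 434. In each, the remaining split separated the most and the split by replicate number the fewest. How far the label split exceeds replicate number depends on the definition, so the exchange stays open. The 24 calls of the PTX effect take these labels as given and may not hold if they are wrong. Without both arrays the 9 genes named above still differed by 0.97 to 1.62, but there PTX cannot be told apart from the sets. Also open are 2 cultures or days that each gave 2 basal, 1 TRAP and 1 TRAP after PTX array: the nearest arrays of the 2 sets were 0.51 (log2) apart in the cell cycle median, and the labels name no day.

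All 24 probe sets of the PTX effect were higher with PTX. Quantile normalization called 33, of which 30 were higher and 3 lower, and median centring called 20, all higher. The median difference of the 24, 1.31, has a part of 0.70 from the stimulated arrays and of 0.55 from the basal arrays, which were lower in the PTX experiment. With the array sets as a block 18 were called, over the bound of 12 set before this count, though not before the arrays' values of these genes, were seen; 10 of the 18 were among the 24. That bound was set aside because the 2 basal groups lie wholly in different sets, so the block compares TRAP replicate 2 with TRAP after PTX replicate 2 and a response that differs between the sets looks the same as an effect of PTX. The sets stay open for all 24. Gene length may play a part: over all kept genes its rank correlation with the difference was 0.0693, under the bound of 0.1 set beforehand as evidence against it, but that bound was set aside because all genes dilute a pattern of 17. Their own median length was at percentile 82.2, where 2 of 10000 random sets matched on signal were as long, so gene length stays open beside the toxin itself.

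The 12 arrays were divided in 100 of 462 possible splits, in a fit of experiment and label. For probe sets called in the averaged response the real split gave 2040. Only 1 of the 100 splits (itself) gave as many, and the highest other gave 164. A random division of these arrays can thus be excluded as the source of this count. Chance differences between cultures are not covered, since the labels do not say that replicates came from separate cultures. The other splits also leave the stimulation effect in the residual spread, which lowers their counts. For the number of lists these splits cannot decide on chance. The real split called 11, 19 of the 100 gave as many, and the highest other gave 14. Every other split with at least 11 lists kept 8 or 10 of the 12 arrays on the side of their label. Such splits hold part of the stimulation effect. Splits with the stimulated arrays spread evenly over both sides called up to 9 lists.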

How the results depend on the processing

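The block for the array sets, the fit without 2 arrays and the crossed replicate block were chosen only after the result was seen. Where no cause is given below, the cause was not tested. Of the alternative values of counts and measures, 374 stayed close and 99 moved. Of 4155 values of 174 results for named genes, 3834 kept direction and call, 321 lost the call and 0 reversed.

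Leaving out 1 array, which leaves fewer samples, gave these ranges: thrombin 342 to 918 probe sets, TRAP 208 to 759, TRAP after PTX 149 to 539, averaged 1628 to 2354, thrombin minus TRAP 33 to 140, PTX effect 0 to 47, and basal groups 5878 to 7825. Called lists ranged from 11 to 14 (thrombin), 8 to 12 (TRAP), 6 to 12 (TRAP after PTX), 11 to 14 (averaged), 6 to 12 (thrombin minus TRAP) and 2 to 7 (PTX effect). The correlation of responses ranged from 0.340 to 0.399 (thrombin and TRAP), 0.277 to 0.397 (thrombin and TRAP after PTX) and 0.328 to 0.423 (both TRAP responses), and the retained response from 0.202 to 0.459 (TRAP) and 0.174 to 0.417 (TRAP after PTX).

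The correlations of thrombin with TRAP and with TRAP after PTX were 0.345 and 0.315 at a pseudocount of 1, and 0.444 and 0.415 at 64, where the retained response was 0.24 and 0.24. Without a filter the 3 correlations were 0.270, 0.230 and 0.262, the retained TRAP response 0.32 and the PTX effect 13 probe sets; with the filter at the 60th percentile they were 0.490, 0.472 and 0.509. Without an intensity trend the counts were 334 (TRAP after PTX), 23 (thrombin minus TRAP) and 0 (PTX effect, limma), with 0.33 and 0.35 retained. Array weights gave 1111 (TRAP) and 305 (TRAP after PTX). Fits of the compared arrays alone, with fewer samples, gave 576 (thrombin), 260 (TRAP after PTX) and 1 (PTX effect). A further threshold of 2-fold left 179, 170, 127, 94 and, among basal groups, 2458. All 6 basal arrays as the control gave 6573, 2570 and 2961, since the basal groups differ, and stimulated arrays compared directly 6843 for thrombin minus TRAP, 65 of them shared with the 99. The lists called with an estimated correlation were 7, 1, 1, 7, 0 and 0. Fry called 13 (thrombin), 11 (TRAP), 10 (TRAP after PTX), 12 (averaged), 1 (thrombin minus TRAP) and 0 (PTX effect). Over probe sets called with TRAP the retained response was 0.75 and 0.40, since the probe sets were chosen there, and over those that changed 2-fold with thrombin 0.70 and 0.60.

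With the array sets as a block the correlations with TRAP after PTX were 0.333 (thrombin) and 0.311 (TRAP). Without the 2 arrays outside the set of their own basal arrays the counts were 166 (TRAP after PTX) and 9 (PTX effect), the correlations of thrombin with the others 0.376 and 0.305, and the retained TRAP response 0.34. Deviations of equally numbered basal and stimulated arrays correlated with r of 0.134, 0.104 and 0.0217, so the numbers show little pairing. The crossed replicate block gave 106 (thrombin minus TRAP) and 19 (PTX effect). Low signal limits the precision of dim genes, and the number of arrays that of all.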

Other observations

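The tests of the other receptor targets were planned before their values were seen, and the test of an already active receptor was chosen only after the result was seen.

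Of 6 measured targets of the aryl hydrocarbon receptor, which senses planar aromatic compounds, 4 rose with TRAP (Tiparp, Ahrr, Cyp1b1 and Nfe2l2), and Nqo1 and Slc7a5 did not pass. With thrombin these 6 did not pass limma's test (lowest adjusted p = 0.175, Cyp1b1), and no list test was made. Tiparp rose by 1.54 with TRAP and 1.699 with TRAP after PTX, and Ahrr by 1.16 and 1.29, while with thrombin they measured -0.15 and -0.21. Cyp1b1, an oxidase gene, rose by 0.98 and 0.77, from signals of 3737 to 7366 and 4915 to 8420, and measured -0.27 with thrombin. The thrombin and TRAP responses differed in Tiparp (-1.69), Ahrr (-1.37) and Cyp1b1 (-1.24), with limma's adjusted p of 0.000207, 0.00376 and 0.00172. The list of targets was written after the values of Tiparp and Ahrr were seen and before those of the others; that only targets past the signal filter count as measured was settled after all values were seen.

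A candidate explanation is a ligand of this receptor that came with the peptide. The 4 other measured targets, Cyp1b1, Nqo1, Nfe2l2 and Slc7a5, had a median of 0.57 with TRAP, 0.65 with TRAP after PTX and -0.03 with thrombin, which is what such a ligand predicts. Thrombin was given in a separate experiment, so cells that respond differently could give the same medians. Among them Slc7a5 measured 0.11 and 0.13, and Nqo1 passed with TRAP after PTX (1.22) and missed with TRAP (0.60, adjusted p = 0.0587). A receptor already active in unstimulated cells of the thrombin experiment stays open: basal thrombin minus basal TRAP was 2.18 for Tiparp, 0.13 for Cyp1b1 and -1.26 for Ahrr. Signalling by the peptide's own receptor was not tested as a separate cause, and no array had peptide vehicle alone by the labels.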
